A study of Caenorhabditis elegans with 10 samples.

How the data were processed

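Whole young adult Caenorhabditis elegans were measured on 10 Affymetrix C. elegans whole-genome arrays, 1 array per strain or RNAi feeding. Per the labels, animals were grown for 2 generations on plates and then in liquid culture, adults were enriched by sucrose centrifugation, and the total RNA of 3 biological replicates was pooled for each array. The authors deposited log2 values, read as log2 from their range of 1.43 to 16.01, and how these were summarised and normalized is not given in the sources used here. The deposited array medians lay between 5.88 and 6.01. Signal over background per array was not used here, and the number of arrays limits the precision.

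The arrays were placed in 4 groups from their labels: the wild type grown on OP50 plates and then K12 liquid culture (1 array, the labelled control of the missense mutants), the wild type on HT115 (1 array, the labelled control of the RNAi animals), the missense mutants gas-1, mev-1 and isp-1 (3 arrays, K12 culture), and animals fed RNAi bacteria against nduf-6, nuo-5, ndua-13, ndab-1 or ndub-7 (5 arrays, HT115 culture with 5 mM IPTG). The label of the HT115 wild type names neither IPTG nor an empty vector.

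The rules below were fixed before the data were examined. Because the array medians differed by 0.13, more than the limit of 0.1, values were quantile normalised over the 10 arrays. Of 22625 probe sets, 77 controls were left out, and 20766 of the rest carried 1 gene symbol. Another 887 carried several symbols and 895 carried none, and these were left out. By Entrez identifier, 20701 probe sets matched the RefSeq table of assembly WBcel235, which was used for names only. Probe sets with a mean log2 value under the 25th percentile, 2.60, were left out, which kept 16911. A gene with several probe sets was given by the one with the highest mean, and 12641 genes were tested.

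Differences were tested with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, a mean-variance trend and Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. The comparison of all 8 mutants with both wild types had terms for culture and for mutant, with 7 residual degrees of freedom. The missense and RNAi comparisons with their own wild types, and the difference between these responses, came from a fit with 4 groups and 6 residual degrees of freedom. Each wild type was a single array and was assumed to vary like the other groups, so the p-values measure differences against the spread between mutants of 1 kind, which holds real differences between mutants as well as noise. Single arrays were compared by size only, without p-values.

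Of 39 gene lists fixed from textbook knowledge, 38 had at least 4 measured members. The list of mitochondrial DNA-encoded genes had no matched member and was not analysed here. The fixed rules named the comparisons with wild type for the lists, and the response difference was added to them later. Lists were tested with limma's camera, at a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry, adjusted over the 38 lists. The camera test compares a list with the other genes. The directional p of fry tests whether a list's genes move, on balance, in 1 direction, and its mixed p whether they change in either direction, and neither compares a list with other genes. For single arrays, a list's median was ranked among 10000 random lists of the same size matched on mean level.

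Counts of genes moved at least 1.5-fold in the same direction in all 8 mutants, and the correlation of the missense and RNAi responses, were set against all 24 choices of 1 control array per culture. The genes named below were chosen by rule: the mutated and targeted genes, up to 10 genes per direction past the threshold and moved in the same direction in each mutant of the comparison, or the 5 with the smallest p where fewer than 5 passed, up to 4 members of each list with the smallest p, the 5 highest and 5 lowest ratios of each single array among genes whose higher value lay above the median of all values, and the 5 smallest p per direction of the response difference. Any other gene is named as chosen after its values were seen.

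The fits were tested on 10 simulated data sets with the real levels and spreads, in which 200 of 12641 genes were changed. Changes of 2-fold and 4-fold were recovered at 45.9% and 78.1% in the comparison of 8 mutants with wild type, at 17.6% and 53.6% in the missense comparison, at 20.1% and 58.1% in the RNAi comparison, and at 5.9% and 29.0% in the response difference, with 7, 4.8, 3.6 and 2 false calls on average. A list shifted by 0.5 (log2) was called in 10 of 10 simulations of each comparison at the preset correlation, and in at least 9 of 10 with an estimated one. The simulated genes varied independently, whereas the complex I list, the one shifted, had an estimated correlation of 0.47 in the 8 mutants. Its real median there was 0.17, smaller than the shift. The simulations therefore do not show how the list tests behave on correlated genes.

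Alternatives covered the deposited values, median centring, other filters, the mean or all of a gene's probe sets, other variance models, array weights, other thresholds, subsets of arrays and leaving out each array in turn. For lists, genes moved in the same direction and the correlation of the responses, only mutant arrays were left out in turn. Tables were prepared in Python 3.11.15.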

Results

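The data were log2 expression values of 12641 genes in young adult worms on 10 arrays, covering 8 strains or RNAi feedings labelled as mutants of the mitochondrial electron transport chain and 2 wild types. The missense mutants were gas-1 (complex I), mev-1 (complex II) and isp-1 (complex III), with 1 wild type grown on K12 bacteria. The label of the isp-1 array names isp-1, its allele and complex III but cites T07C4.7, the sequence name of mev-1 (that of isp-1 is F42G8.12), so values given for isp-1 rest on the rest of that label. The RNAi animals had 5 different complex I subunits targeted, with 1 wild type grown on HT115 bacteria. Each array held RNA pooled from 3 biological replicates, so no strain had a replicate array. The series was designed to show which metabolic pathways lie downstream of the mutations.

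The mutated and targeted genes were examined first, in each array. In the array labelled nuo-5 RNAi (Y45G12B.1, a core complex I subunit), nuo-5 stood at -0.95 (log2) against the HT115 wild type, 51.9% of its level and the lowest of the 10 arrays. In the array labelled ndua-13 RNAi (C34B2.8), the target stood at -0.51, or 70.5%, also the lowest of the 10. In the array labelled nduf-6 RNAi (F22D6.4) the target stood at -0.25, or 83.9%, and in the array labelled ndub-7 RNAi (D2030.4) at -0.18, or 88.5%, while ndub-7 stood at -0.59 in the array labelled nduf-6 RNAi. The target of the array labelled ndab-1 RNAi (Y56A3A.19) went against its label: ndab-1 stood at 1.08, 211% of the wild-type level and the highest of the 10 arrays, although a lower-signal probe set of this gene gave -0.18. RNAi arrays are therefore named by their labels throughout. A missense mutation need not change the mRNA level, so the values of gas-1 (0.39), mev-1 (-0.09) and isp-1 (0.18) in their own mutants check nothing.

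**Figure D1:**
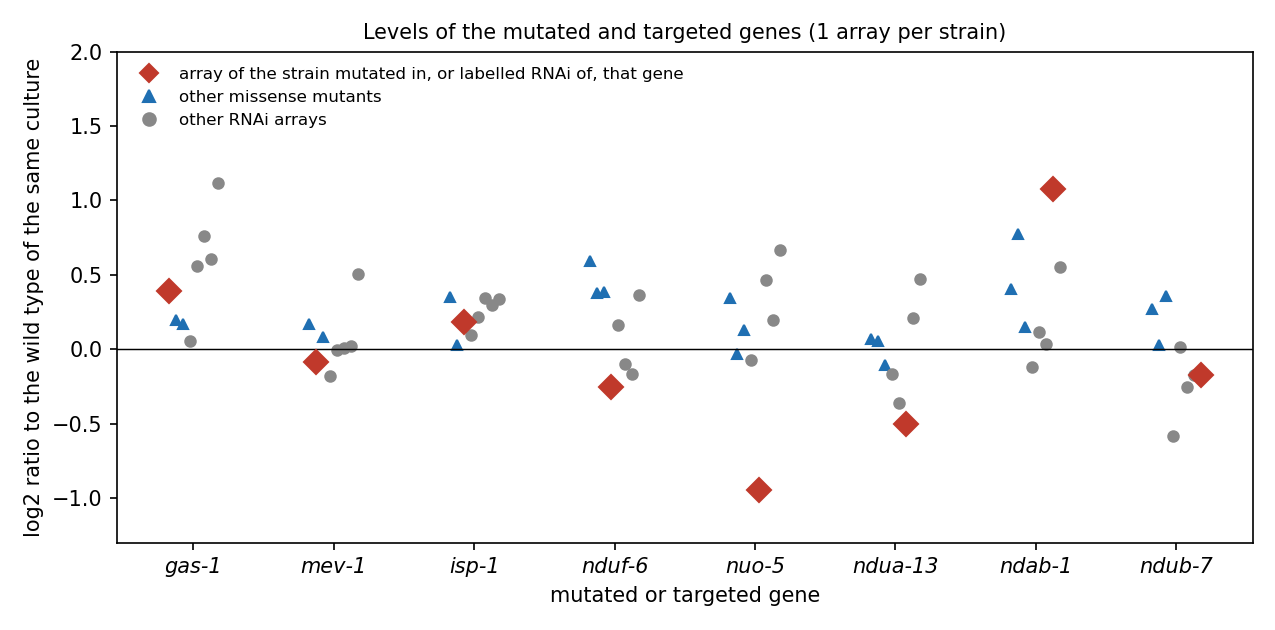
Log2 ratio of each mutated or targeted gene (horizontal axis) to the wild type of the same culture, in each of the 8 mutant arrays (points, 1 array each). Diamonds mark the array of the strain mutated in, or labelled as RNAi of, that gene: nuo-5 stood at -0.95 and ndua-13 at -0.51 in their own arrays, and ndab-1 at 1.08.

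In the joint comparison of the 8 mutants with both wild types, several lists of metabolism and protein folding were higher by small amounts, while glycolysis, complex II, the glyoxylate cycle and fatty acid synthesis did not pass. The complex I list rose by a median of 0.17 (log2; 26 of 31 members higher), although it stood at -0.16 in the array labelled nduf-6 RNAi (21 of 31 lower), and the complex III list by 0.21 (11 of 12), with ucr-2.2, a core protein of complex III, at 0.85 ± 0.30 (SE, 8 mutants against 2 wild types). The tricarboxylic acid (TCA) cycle list rose by 0.20 (22 of 25), and the pentose phosphate list, which supplies NADPH and ribose, by 0.36 (5 of 6). The mitochondrial unfolded protein response list rose by 0.26 (12 of 14; -0.05 in the array labelled nuo-5 RNAi), with hsp-6, the mitochondrial Hsp70, at 0.82 ± 0.21 and higher in 8 of 8 mutants. The cytosolic heat shock list rose by 0.54 (10 of 10; -0.32 in the array labelled ndub-7 RNAi), with hsp-16.2 at 1.74 ± 0.58. These 6 lists had camera adjusted p-values between 0.000751 and 0.00538, and adjusted p = 0.636 to 0.651 with an estimated correlation. Complex II, which did not pass, had the same median as the TCA cycle list (0.20, 4 of 5 members higher). The lists share genes and differ in size (5 and 25 members), so they do not differ in level.

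Another 4 lists that rose in the 8 mutants were neuron markers (0.31, 33 of 42), UDP-glucuronosyltransferases, enzymes that conjugate foreign compounds (0.32, 42 of 55), cytosolic ribosomal proteins (0.05, 48 of 61) and fatty acid beta-oxidation (0.15, 26 of 36). Their camera adjusted p-values lay between 0.000222 and 0.00920, and adjusted p = 0.636 to 0.651 with an estimated correlation. Among their members, ugt-61 stood at 1.85 ± 0.48, ugt-62 at 2.09 ± 0.55 and acdh-1, an acyl-CoA dehydrogenase, at 2.64 (SE 1.1). The neuron list also differed between the wild types, at 0.91 higher in the K12 array, and stood between -0.16 and -0.02 in the missense mutants. A further 10 lists passed but lost the call under at least 1 of 13 other settings: complex IV (0.16), ATP synthase (0.11), branched-chain amino acid breakdown (0.15), mitochondrial ribosomal proteins (0.07), glutathione S-transferases (0.17), metallothioneins and zinc response (0.11) and the methionine cycle (0.14; -0.11 in the missense comparison, where gas-1 and mev-1 lay below 0) rose, and pharynx muscle markers (-0.30, 10 of 12 lower), body wall muscle markers (-0.18, 14 of 18 lower) and embryonic genes (-0.24, 10 of 14 lower) fell. With an estimated correlation these 10 had camera adjusted p = 0.636 to 0.827. None of the 13 settings left out a wild type. Of the 20 lists, 5 had a median on the called side in 8 of 8 mutant arrays: complex III, the TCA cycle, the pentose phosphate pathway, UDP-glucuronosyltransferases and beta-oxidation. Mitochondrial ribosomal proteins had a median below 0 in the arrays labelled nduf-6, ndua-13 and ndab-1 RNAi. Body wall muscle markers were above 0 in those labelled ndua-13, ndab-1 and ndub-7 RNAi, and pharynx muscle markers in nduf-6 and ndub-7 RNAi. Without gas-1 the number of called lists went from 20 to 13, and without isp-1 to 12.

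Of single genes, 2 passed the limma threshold over all 12641 genes, both lower. The gene mps-2, an accessory subunit of potassium channels, fell by 0.81 (SE 0.08, adjusted p = 0.0361) and was lower in 8 of 8 mutants. The gene fil-2, named for a lipase family induced by fasting, fell by 2.02 (SE 0.22, adjusted p = 0.0361), also in 8 of 8, to mean levels of 2.2 and 2.44 in the missense and RNAi arrays, under the filter level of 2.60, so the size of its fall is uncertain. Genes with the smallest p that did not pass stood at 1.90 for F22H10.2, 1.74 for the C-type lectin clec-265, 2.17 for the transporter pgp-9, 0.50 for tin-10, a small chaperone of mitochondrial protein import, and 2.32 for R11D1.3. On the lower side they stood at -2.98 for pro-3, -0.91 for lgc-20 and -1.66 for fbxa-71, with limma adjusted p-values between 0.0661 and 0.130. The sizes for pro-3 and lgc-20 are uncertain. The missense and RNAi means of pro-3 (2.59 and 2.65) and the RNAi mean of lgc-20 (2.56) lay near or under the filter level. At an unadjusted p of 0.05, 297 genes were higher and 577 lower, against 632 expected by chance.

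Of the list members, 0 passed limma's test over all genes, while 7 passed when adjusted over the list alone. They were rpia-1 (0.55 ± 0.13) and tkt-1 (0.48 ± 0.16) of the pentose phosphate pathway, cdr-4 (1.89 ± 0.45) and cdr-2 (1.88 ± 0.59), of a family named for its response to cadmium, the cuticle collagens col-181 (-0.73 ± 0.13) and col-19 (-0.76 ± 0.15), and the epidermal antimicrobial peptide nlp-29 (-1.15 ± 0.17). Each of these 7 moved in the same direction in 8 of 8 mutants. The gene count rested on single arrays: it was 50 without the K12 wild type, which leaves the RNAi comparison by construction, 4 without the HT115 wild type, 0 without gas-1, 5 without mev-1 and 1 without isp-1. It was 1, higher, without the array labelled nduf-6 RNAi, 7 without ndab-1 RNAi, and 0 without nuo-5, ndua-13 or ndub-7 RNAi, where limma called 874 genes at an unadjusted p of 0.05 with all arrays. Neither mps-2 nor fil-2 was among the genes called without the HT115 wild type, isp-1 or the array labelled nduf-6 RNAi.

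**Figure D2:**
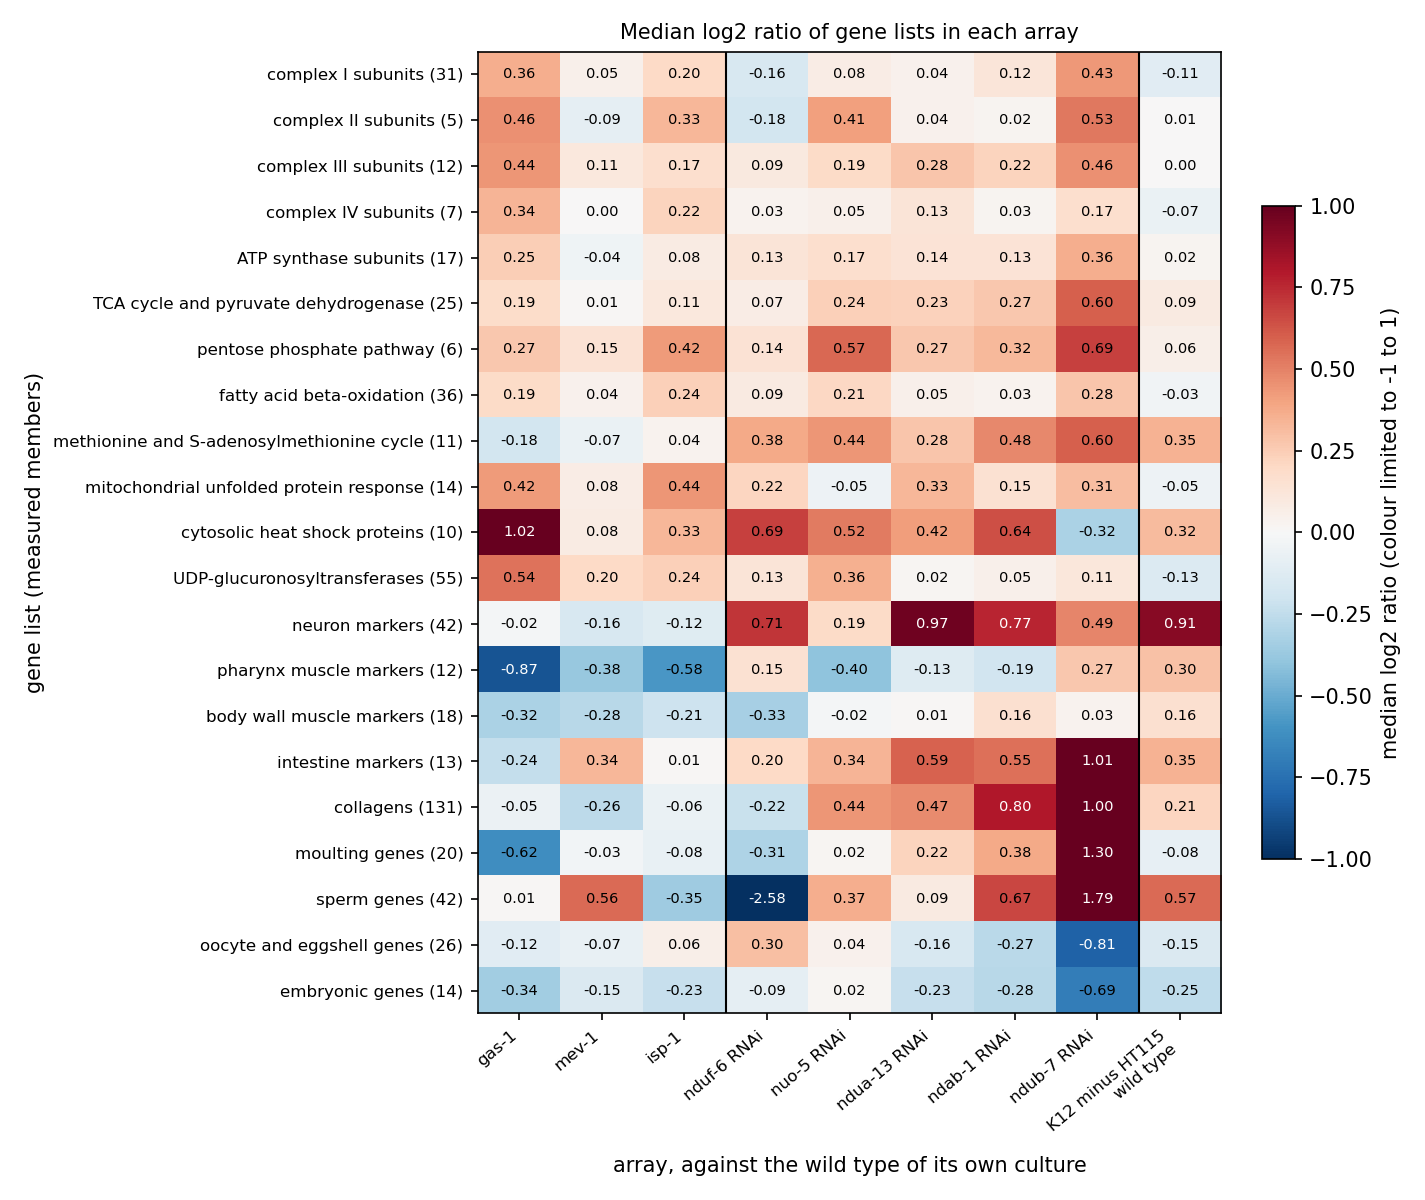
Median log2 ratio of 21 gene lists (vertical axis, measured members in brackets) in each mutant array against the wild type of its culture, and of the K12 against the HT115 wild type (horizontal axis, 1 array per column, colour limited to -1 to 1). Complex III and the pentose phosphate pathway were above 0 in each of the 8 mutant arrays, while the neuron list stood at 0.91 in the K12 wild type and between 0.19 and 0.97 in the RNAi arrays.

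The missense mutants were compared with the K12 wild type to ask what point mutations in complexes I, II and III shared. Lists of complex I and of mitochondrial translation and protein folding were higher: the complex I list rose by a median of 0.21 (30 of 31 members), mitochondrial ribosomal proteins by 0.12 (49 of 57) and the mitochondrial unfolded protein response by 0.32 (13 of 14), with hsp-6 at 0.76 ± 0.33 (SE, 3 mutants against 1 wild type). Cytosolic ribosomal proteins rose by 0.10 (58 of 61) and UDP-glucuronosyltransferases by 0.37 (43 of 55), with ugt-61 at 2.81 ± 0.58 and ugt-13 at 2.85 ± 0.96. Muscle genes were lower: pharynx muscle markers fell by 0.63 (12 of 12 lower), with the myosin gene myo-2 at -0.66 ± 0.35, and body wall muscle markers fell by 0.30 (18 of 18 lower), with the paramyosin gene unc-15 at -0.36 ± 0.18. These 7 lists had camera adjusted p-values between 3.17e-05 and 0.00219, and adjusted p = 0.868 to 0.923 with an estimated correlation. The 3 mutants differed in size: the complex I median was 0.36 in gas-1, 0.05 in mev-1 and 0.20 in isp-1, and the pharynx median -0.87, -0.38 and -0.58. The K12 wild type itself stood apart from the HT115 wild type in the direction that favours these calls for pharynx muscle (0.30), body wall muscle (0.16), mitochondrial ribosomal proteins (-0.20), complex I (-0.11) and UDP-glucuronosyltransferases (-0.13). Markers of stage also differed: moulting genes stood at -0.62 in gas-1 (16 of 20 lower), and sperm genes at 0.56 in mev-1 (40 of 42 higher) and -0.35 in isp-1 (39 of 42 lower).

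Another 6 lists passed in the missense mutants but lost the call under at least 1 of 13 other settings: complex III (0.24), complex IV (0.19), cytosolic heat shock proteins (0.22), the pentose phosphate pathway (0.30) and fatty acid beta-oxidation (0.16) rose, and collagens fell (-0.11, 77 of 131 lower). With an estimated correlation their adjusted p was 0.868 to 0.923. The TCA cycle (0.07, camera adjusted p = 0.0881), ATP synthase (0.10, 0.303) and complex II (0.28, 0.480) did not pass. Without gas-1, 8 of the 13 lists were called.

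Of single genes, 4 passed in the missense mutants, moved in the same direction in 3 of 3. ZK218.5 fell by 6.95 (SE 0.51, adjusted p = 0.00950), from 9.18 in the K12 wild type to 2.23 ± 0.53 (SD, n = 3), under the filter level of 2.60, while in the RNAi animals it stood at 2.8 (SE 0.49, adjusted p = 0.0785, not passing) against their wild type. pro-3 fell by 1.88 (SE 0.17, adjusted p = 0.0174) and the cytochrome P450 gene cyp-13A1 fell by 1.15 (SE 0.11, adjusted p = 0.0189), while C08F11.7 rose by 1.96 (SE 0.18, adjusted p = 0.0174). With pro-3 at 2.59 in the mutants and C08F11.7 at 2.15 in the wild type, neither shown to be above background, the sizes of these changes and of the fall of ZK218.5 are uncertain. For cyp-13A1 the K12 wild type stood alone (3.97), with the HT115 wild type (2.8) at the level of the missense (2.82) and RNAi (2.81) means. The spread of pro-3 and cyp-13A1 came from arrays near the filter level, so their p-values may be too small. Among the genes that did not pass, the ribonuclease H gene rnh-1.3 stood at 3.94, F19B2.5 at 2.92 and F35F10.7 at 2.52. C09B8.4 stood at 2.26, an uncertain size, since the K12 wild type stood at 2.01, under the filter level. On the lower side anp-1 stood at -1.42 and mps-2 at -0.82. Adjusted over the list alone, cyp-13A1 of the cytochrome P450 list (adjusted p = 0.000306) and the C-type lectin clec-153 (-0.60 ± 0.10, adjusted p = 0.0344) passed. The count of 4 was 10 without gas-1, 9 without mev-1 and 1 without the array labelled nuo-5 RNAi, which enters only through the shared spread, and limma called 385 genes at an unadjusted p of 0.05, fewer than the 632 expected by chance.

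The RNAi animals were compared with the HT115 wild type to ask what animals fed RNAi against single complex I subunits shared, although a lower target was not seen in each array. Genes of the neuron list rose by a median of 0.61 (40 of 42 members), with the vesicular glutamate transporter eat-4 at 1.24 ± 0.24 and the neuropeptide genes flp-4 at 1.54 ± 0.45 and flp-16 at 1.42 ± 0.43 (SE, 5 RNAi arrays against 1 wild type). Collagens rose by 0.52 (98 of 131), at 0.44 to 1.00 in 4 arrays but -0.22 in the array labelled nduf-6 RNAi (78 of 131 lower), with col-41 at 4.22 ± 1.05 and dpy-8 at 4.31 ± 1.09. The methionine cycle rose by 0.41 (10 of 11), with the S-adenosylmethionine synthetase sams-1 at 1.44 ± 0.52, the TCA cycle list by 0.31 (22 of 25) and intestine markers by 0.49 (11 of 13). These 5 lists had camera adjusted p-values between 4.49e-12 and 0.0278, and adjusted p = 0.833 with an estimated correlation. The wild types themselves differed in the same lists: the K12 array stood above the HT115 array by 0.91 for neurons, 0.21 for collagens, 0.35 for the methionine cycle, 0.09 for the TCA cycle and 0.35 for the intestine.

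Another 5 lists passed in the RNAi animals but lost the call under at least 1 of 12 other settings: the pentose phosphate pathway (0.44), branched-chain amino acid breakdown (0.25), ATP synthase (0.18), complex III (0.27) and cytosolic heat shock proteins (0.50; -0.32 in the array labelled ndub-7 RNAi) rose, with adjusted p = 0.833 with an estimated correlation. Complex I itself did not pass (median 0.07, camera adjusted p = 0.189), and its member nduv-2, a subunit of the NADH-binding part, stood at -0.94 ± 0.17 and was lower in 5 of 5. Adjusted over the list alone, nduv-2 (adjusted p = 0.0188), eat-4 (0.0312), rpia-1 (0.0187), nlp-29 (0.0277), col-150 (0.0163) and cyp-14A2 (0.00888) passed, and over all genes col-150, cyp-14A2 and nlp-29 did. Markers of stage moved with these lists: in the array labelled ndub-7 RNAi the median was 1.79 for sperm genes, 1.3 for moulting genes, 1.00 for collagens and -0.81 for oocyte genes, and in the array labelled nduf-6 RNAi it was -2.58 for sperm genes. Without the array labelled nuo-5 RNAi, or without ndub-7 RNAi, 6 of the 10 lists were called.

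Of single genes, 50 passed in the RNAi animals, 5 higher and 45 lower (90%), each in the same direction in 5 of 5 arrays. The 5 ratios share 1 wild-type array, so this agreement is not replication. The higher ones were the cytochrome P450 gene cyp-14A2 (3.18 ± 0.49), pgp-9 (3.16 ± 0.44), the collagen col-150 (2.63 ± 0.39), klu-1 (1.58 ± 0.24) and F28F9.3 (1.19 ± 0.10). For cyp-14A2 and F28F9.3 the HT115 wild type stood at 2.07 and 1.82, under the filter level of 2.60, so the sizes of these rises are uncertain. The lowest ratios were those of pro-3 (-3.96 ± 0.16), the hedgehog-related gene grl-11 (-3.0, SE 0.10), drd-10 (-2.49 ± 0.11), fil-2 (-2.43 ± 0.24) and the small heat shock gene hsp-12.1 (-2.42 ± 0.38). They were followed by F35E12.4 (-2.27), D2063.1 (-2.15), the T-box gene tbx-43 (-2.15), T02G5.3 (-1.96) and the F-box gene fbxa-211 (-1.95). T02G5.3 has 3 probe sets, and its value was as small as -0.87 under the alternatives run, with the call lost in 2 of 19. The RNAi means of pro-3 (2.65), grl-11 (2.49), drd-10 (2.92), fil-2 (2.44) and F35E12.4 (2.44) lay near or under the filter level of 2.60, so the size and order of these ratios mainly follow the level of the HT115 wild type. Adjusted p-values of these 15 genes lay between 1.58e-05 and 0.0487. For grl-11, drd-10 and F35E12.4 the RNAi SD (0.058, 0.060 and 0.055) came from arrays near the filter level. The HT115 wild type stood at 5.49, 5.41 and 4.71, where its spread was not measured, so these p-values may be too small. The 50 genes had a median level of 3.23, against 7.55 for all genes tested, and the HT115 wild type was the outermost of the 10 arrays at 50 of 50. The count was 33 without the array labelled ndua-13 RNAi, 14 with the HT115 arrays alone in the fit, and 91 without the arrays labelled nduf-6 RNAi and ndub-7 RNAi, an alternative chosen after seeing the data.

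Whether the missense and RNAi responses differed was tested directly, as the difference of the 2 responses, each against its own wild type. Genes of the neuron list fell in this difference by a median of 0.77 (missense minus RNAi, 39 of 42 members), collagens by 0.59 (98 of 131) and the methionine cycle by 0.56 (11 of 11), with eat-4 at -1.24 ± 0.34 and sams-1 at -1.67 ± 0.75. Pharynx muscle (-0.45), body wall muscle (-0.27), moulting (-0.54) and intestine (-0.35) lists also fell but lost the call under at least 1 of 12 other settings. The 7 lists had camera adjusted p-values between 1.57e-12 and 0.0462, and adjusted p = 1.00 with an estimated correlation. Without gas-1, 4 lists were called.

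Of single genes, 6 passed in the response difference, 5 higher and 1 lower. They were grl-11 (2.92 ± 0.14), drd-10 (2.52 ± 0.16), pro-3 (2.09 ± 0.24), F35E12.4 (1.79 ± 0.14), H20J04.6 (1.2, SE 0.12) and, lower, ZK218.5 (-9.75 ± 0.71), with limma adjusted p-values between 0.000399 and 0.0443. The genes grl-11 and drd-10 stood at 5.49 and 5.41 in the HT115 wild type and between 2.41 and 2.92 in the K12 wild type and in the means of both mutant groups. For F35E12.4 (4.71) and H20J04.6 (3.72) the HT115 wild type also stood above the K12 wild type (2.99 and 2.53) and both mutant means (2.44 to 2.52). The spread of these genes came from arrays near the filter level, so their p-values may be too small. For pro-3 the mutant means were alike (2.59 and 2.65), and its difference matches the gap between the wild types (6.61 on HT115, 4.47 on K12). For ZK218.5 the size is uncertain, with a missense mean of 2.23, and it includes a gap between the wild types (9.18 on K12, 7.07 on HT115). Genes that did not pass were F28F9.3 (-1.18), cyp-13A1 (-1.17), cog-1 (-1.23) and Y50D4C.5 (-0.89). The sizes for F28F9.3 and Y50D4C.5 are uncertain, with the HT115 wild type at 1.82 and 2.31, under the filter level of 2.60. In the list of complex I subunits, nduv-2 (1.31 ± 0.25) passed adjusted over the list alone (adjusted p = 0.0251) and not over all genes. In the fatty acid synthesis list the elongase elo-1 (-0.91 ± 0.21, adjusted p = 0.0463) did, and in the cytochrome P450 list cyp-13A1 (adjusted p = 0.00300), where the K12 wild type alone stood apart (3.97, others 2.8 to 2.82). At an unadjusted p of 0.05 limma called 535 genes.

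Without any estimate of spread, 58 genes were at least 1.5-fold from their own wild type in the same direction in all 8 mutants, 19 higher and 39 lower. Among the lower ones, mean log2 ratios were -1.21 for nlp-29 (SD 0.34 over 8 mutants), -2.13 for the antimicrobial peptide gene cnc-7 (SD 0.78) and -0.77 for the adult collagen col-19 (SD 0.20). The ratio of mps-2 varied least of the 58, between -0.85 and -0.74 (SD 0.04). Among the higher ones were cdr-4 (1.90, SD 0.63), clec-265 (1.77, SD 0.53) and the cytochrome P450 gene cyp-33C8 (2.05, SD 1.04). Chosen after their values were seen, the insulin-like peptide gene ins-35 (2.81, SD 1.19) and the heme-responsive gene hrg-7 (2.61, SD 1.51) were higher, and dod-22 (-2.91, SD 1.21) and nlp-28 (-1.3, SD 0.46) lower. As many genes or more were found for 3 of the 24 choices of control arrays, the wild types included. The count was 94 without isp-1 and 95 without the array labelled nduf-6 RNAi.

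Across genes, which are not independent replicates, the mean missense and mean RNAi responses correlated at r = 0.141 (Spearman's rho 0.177). As large an r came from 5 of the 24 choices of control arrays, and the other 23 gave -0.202 to 0.223. Without gas-1 the correlation was 0.0761. The 15 single pairs of a missense mutant and an RNAi array, which share no array, gave r between -0.0688 (mev-1 with the array labelled ndua-13 RNAi) and 0.297 (gas-1 with nuo-5 RNAi). Mutants that share a wild type gave r of 0.396 to 0.561 among the missense mutants and 0.105 to 0.880 among the RNAi arrays, against 0.504 simulated for a shared control with no effect. Their covariances were 0.145 to 0.168 and 0.0600 to 0.471, against a simulated 0.238. With 1 control array per culture the controls could not be split, so part or all of these correlations may come from them. Among the missense mutants the covariances, up to 0.168, lay under the value simulated with no effect.

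**Figure D3:**
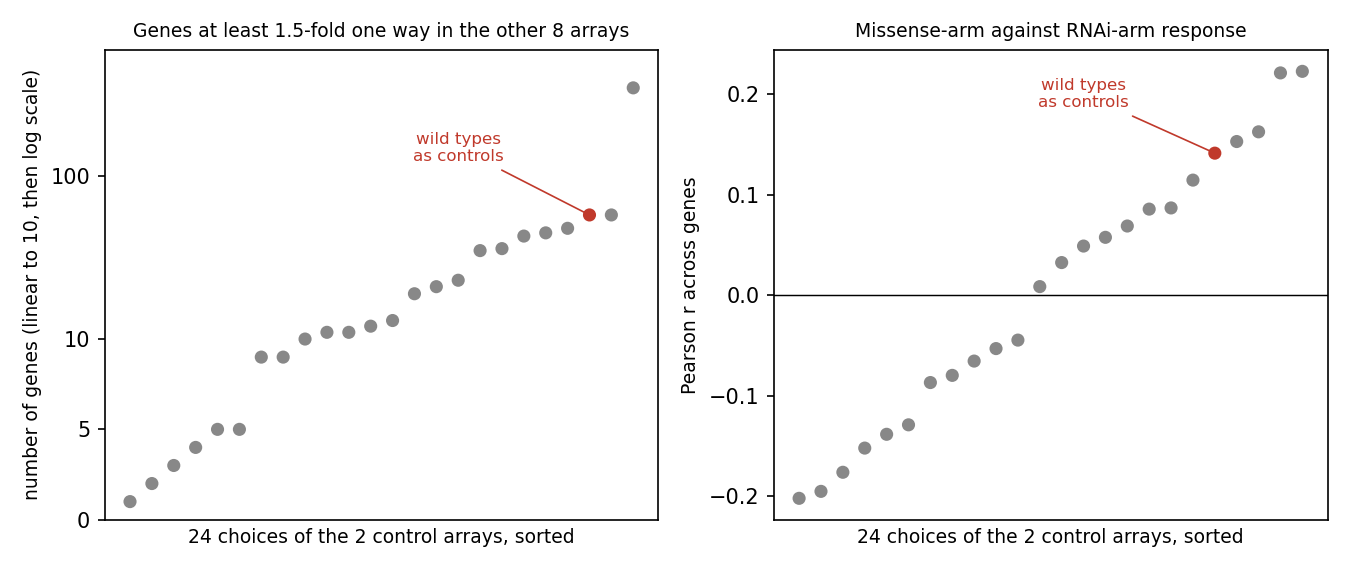
Left, the number of genes at least 1.5-fold in 1 direction in all other arrays (linear to 10, then log scale), and right, Pearson's r across genes between the mean responses of both cultures, for each of the 24 choices of 1 control array per culture (points, sorted). The choice of the wild types gave 58 genes and r = 0.141, against up to 351 genes and 0.223 for other choices.

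Single mutants were compared with their own wild type by size, with no p-value, since there was no replicate array. The 3 missense mutants shared a fall of ZK218.5, with log2 ratios of -6.39 in gas-1, -7.45 in mev-1 and -7.01 in isp-1, to levels near or under the filter level of 2.60. Their largest rises differed: F41C3.1 (6.94) and the infection response gene irg-5 (6.05) in gas-1, and C38D9.2 (8.61) and F15D4.5 (7.33) in mev-1. In isp-1 they were T20D4.12 (6.06), pud-3 (5.08), sysm-1 (4.83) and acdh-1 (4.74). The mev-1 array had scl-12 at -8.55 and the collagen col-37 at -7.44. The lower value was under 2.60 for scl-12 and for clec-210 and dpy-6 below, so the sizes of their ratios are uncertain. In 4 of the 5 RNAi arrays pud-3 had the highest ratio, between 7.04 and 8.80, and in the array labelled nduf-6 RNAi this was clec-210 (6.15). The wild types themselves differed for pud-3 (4.58 on HT115, 7.23 on K12), so part of its RNAi ratios may come from the HT115 array. The lectin gene clec-86 stood between -4.69 and -3.64 in the RNAi arrays other than ndub-7. In the array labelled ndub-7 RNAi the cuticle genes col-90 (6.92) and dpy-6 (6.31) were among the highest and nlp-39 (-6.0) the lowest. Genes at least 2-fold from the own wild type numbered 814 in gas-1, 930 in mev-1 and 586 in isp-1, between 872 and 1276 in 4 RNAi arrays, and 2756 in the array labelled ndub-7 RNAi.

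The wild types of the cultures, which differ in bacteria and have 1 array each, were 2-fold or more apart at 907 genes, 520 higher and 387 lower in the K12 array. The secreted-protein genes scl-13 (6.55), scl-12 (5.26) and scl-11 (4.96) and F57F4.2 (4.84) were highest in K12, and far-3, a fatty acid and retinol binding protein gene (-3.49), and the collagen col-101 (-2.64) lowest, all named by size after their values were seen. Sperm genes stood 0.57 higher in the K12 array (39 of 42 members). The K12 wild type correlated with the arrays labelled ndua-13 RNAi and ndab-1 RNAi at r = 0.988 and 0.989 across genes, and with the HT115 wild type at 0.979.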

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

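The test of RNA quality was chosen after the values it explains had been seen, and the other tests were written after each pattern had been seen but before their own result was.

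Of the 50 genes that passed in the RNAi comparison, 45 were lower than in the HT115 wild type, at a median of -1.49. Part of this direction may be set by low signal and the filter on mean level. For grl-11 and H20J04.6 the K12 wild type and both mutant means lay under the filter level of 2.60 (2.41 to 2.53). They were kept only because the HT115 wild type stood at 5.49 and 3.72, so they could only be called lower. How many of the 45 were kept in this way was not counted. With no filter 293 of 305 calls were lower, so the filter alone does not set the direction. Normalization after deposit is argued against, since 89.5% or more of the calls were lower with the deposited or the median-centred values. The unknown processing before deposit was not varied. Whether complex I deficiency lowers the 45 genes stays open. Their median in gas-1 was -0.036, but the K12 wild type already stood at a median of 3.17. That was 0.56 above the filter level, which left less room than the fall to explain. At 92.0% of the 50 genes (46 of 50) the K12 wild type lay nearer to the RNAi mean than to the HT115 wild type. That goes with a HT115 array apart from the others at these genes. They were chosen for a gap between that array and the RNAi arrays, so the share decides nothing on the cause. Over all genes it was not the array farthest from the others. Its mean r with the other arrays was 0.968, against 0.968 for nduf-6 RNAi, 0.962 for mev-1 and 0.951 for ndub-7 RNAi. The gap may reflect that single array, its animals or its culture, whose label names no IPTG. An effect of feeding RNAi bacteria or of the RNAi itself stays open. The 6 choices of a control array in this culture are too few for a share under 0.05: 2 of 6 gave as many calls, the real value was 50 and the highest other 601, with the array labelled ndub-7 RNAi as the control, which points to a structure of the samples.

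The array labelled ndub-7 RNAi had the highest medians of the RNAi arrays for genes of sperm (1.79) and moulting (1.3) and the lowest for oocytes (-0.81) and embryos (-0.69), none far enough from the other 4 arrays to pass the test for single arrays, and for sperm genes the array labelled nduf-6 RNAi (-2.58) lay farther from the rest. Normalization after deposit is argued against, since the moulting median was 1.2 or more with the deposited and the median-centred values. Processing before deposit is unknown and was not varied. RNA quality is argued against as well, since the difference between 3' and 5' control probe sets lay at most 0.0863 outside the range of the other arrays. A younger stage of these animals stays open: 7 spermatid genes outside the list (gsp-3, gsp-4 and nspd genes) had a median of 1.65 in this array, but over the 8 mutant arrays their medians followed those of the sperm list (r = 0.994), so they restate the pattern and decide nothing. Slower development under the RNAi, which would be biological, and a harvest at another time stay open as well.

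Lists of the respiratory chain and the TCA cycle were higher in the comparison of the 8 mutants with wild type, although complex I stood at -0.16 in the array labelled nduf-6 RNAi. With an estimated correlation the camera adjusted p was 0.651 for complex I, complex III and the TCA cycle. With a stage score (moulting minus oocyte median) as a covariate the complex I median was 0.15 instead of 0.17. The TCA cycle median was 0.19 instead of 0.20. This could not decide on stage, since the score barely separated mutants from wild types across both cultures. It was -3.99, -3.49 and -3.67 in gas-1, mev-1 and isp-1, below their wild type (-3.26). Against the HT115 wild type (-3.67) it was higher in ndua-13, ndab-1 and ndub-7 RNAi (-3.16, -2.62 and -1.39) but not in nduf-6 or nuo-5 RNAi. Normalization after deposit is argued against, since the complex I median was 0.15 or more with the deposited and the median-centred values. Again, the processing before deposit was not varied. Chance cannot be excluded: 5 of the 24 choices of control arrays gave a complex I median as far from 0, where the real value was 0.17 and the highest other 0.31. A response of the mutants to the respiratory defect therefore stays a hypothesis.

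For the other counts, chance could not be excluded for the 2 genes called in the 8 mutants (5 of 24 choices gave as many, highest other 232) or for the 58 genes moved in the same direction (3 of 24, highest other 351). Both highest counts came with mev-1 and the array labelled ndub-7 RNAi as controls, several times the real value, which points to a structure of the samples. For the missense comparison chance could not be excluded either: 4 of 4 choices gave as many calls or more, and 4 choices cannot give a share under 0.05. The wild type gave the fewest calls, 4, against 25 with gas-1, 67 with mev-1 and 11 with isp-1 as the control.

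In 70 values tested within the RNAi group, 9 had 1 array far from the other 4, where chance gives about 3.5 at 1 in 20. The array labelled ndub-7 RNAi was far above the others for ATP synthase (0.36, others 0.13 to 0.17), branched-chain amino acid breakdown (0.46, others 0.19 to 0.26), fatty acid synthesis (0.79, others -0.02 to 0.15) and genes at least 2-fold from wild type (2756, others 872 to 1276). It was far below for cytosolic heat shock proteins (-0.32, others 0.42 to 0.69) and T02G5.3 (-2.40, others -1.89 to -1.79). Single arrays were far from the others for pro-3 (-3.66 in nduf-6 RNAi, others -4.06 to -4.02), hsp-12.1 (-3.16 in ndua-13 RNAi, others -2.34 to -2.18) and D2063.1 (-1.5 in nuo-5 RNAi, others -2.46 to -2.24).

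The missense and RNAi responses differed, by limma's test of the difference, for grl-11 (2.92), drd-10 (2.52), pro-3 (2.09), F35E12.4 (1.79), H20J04.6 (1.2) and ZK218.5 (-9.75). For grl-11, drd-10, F35E12.4 and H20J04.6 the K12 wild type and both mutant means lay between 2.41 and 2.99. The HT115 wild type stood at 5.49, 5.41, 4.71 and 3.72, so these differences may come from that array. For pro-3 the difference matches the gap between the wild types (6.61 on HT115, 4.47 on K12), with mutant means of 2.59 and 2.65, and for ZK218.5 the size is uncertain, with a missense mean of 2.23 and the wild types at 9.18 on K12 and 7.07 on HT115. The call was lost in 12 of 17 alternatives for pro-3, in 7 of 17 for H20J04.6 and in 1 of 17 for F35E12.4. By camera at the preset correlation they differed for the medians of neuron markers (-0.77, where the wild types themselves were 0.91 apart), collagens (-0.59), the methionine cycle (-0.56), moulting genes (-0.54), pharynx muscle (-0.45), intestine (-0.35) and body wall muscle (-0.27), with adjusted p = 1.00 with an estimated correlation.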

How the results depend on the processing

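The fits without the arrays labelled nduf-6 RNAi and ndub-7 RNAi, without ndab-1 RNAi, with a stage score, and the missense lists without mev-1 were chosen after seeing the data. No paired analysis was possible because the arrays of different groups are different strains, each wild type is 1 array, and the replicate numbers pair nothing. The pseudocount alternatives were not run, since the deposited values are already log2. Nothing changed direction in what was run: of 506 values of named genes under alternatives, 358 kept direction and call and 148 lost the call, and of 683 values of called lists, 533 kept the call and 150 lost it, 50 of them with the estimated correlation. Of called lists, 10 of 20 kept the call under the other alternatives run, the estimated correlation apart, in the 8 mutants, 7 of 13 in the missense mutants, 5 of 10 in the RNAi animals and 3 of 7 in the response difference. No list alternative left out a wild type. Without the K12 wild type the 8-mutant fit becomes the RNAi comparison by construction, and without the HT115 one the missense comparison. In the RNAi comparison complex I, the mitochondrial unfolded protein response, UDP-glucuronosyltransferases, cytosolic ribosomal proteins and beta-oxidation did not pass. In the missense comparison the TCA cycle and neuron markers (median -0.11) did not pass. Complex III, cytosolic heat shock proteins and the pentose phosphate pathway passed in both. With the estimated correlation 0 lists were called in each of the 4 comparisons, and fry called 0 lists by its directional p (lowest adjusted p = 0.389, 0.203, 0.725 and 0.978) or its mixed p (0.166, 0.248, 0.339 and 0.997).
The 2 genes called by limma in the 8 mutants became 4 with the deposited values, 12 with no filter, 1 with array weights, 1 with the stage score, 1 (higher, and neither of the 2) without nduf-6 and ndub-7 RNAi, 7 without ndab-1 RNAi, and 0 with median centring, a filter at the 50th percentile, the mean of a gene's probe sets, no trend or no culture term, with 874 at an unadjusted p of 0.05. The 4 of the missense mutants became 2 with median centring, 98 with no filter, 1 with the 50th percentile, 0 with the K12 arrays alone and 385 unadjusted. The 50 of the RNAi animals became 305 with no filter, 0 with the 50th percentile, 220 with array weights, 14 with the HT115 arrays alone, 91 without nduf-6 and ndub-7 RNAi, and 1036 unadjusted. The 6 of the response difference became 251 with no filter, 1 with the 50th percentile, 3 with no trend, 36 with array weights, 14 without nduf-6 and ndub-7 RNAi, and 535 unadjusted. The 58 genes of 1 direction became 282 at 1.2-fold, 12 at 2-fold and 30 with the 50th percentile. Apart from the fewer genes or arrays that these settings leave by construction, the cause was not tested. Leaving out 1 array at a time gave 0 to 50 genes for the 8 mutants (50 without the K12 wild type, where the fit becomes the RNAi comparison by construction), 1 to 10 for the missense mutants, 33 to 69 for the RNAi animals and 4 to 9 for the response difference. For genes of 1 direction, lists and the correlation of the responses, only mutant arrays were left out, and neither wild type. This gave 61 to 95 genes of 1 direction, and 12 to 20, 8 to 18, 6 to 13 and 4 to 9 lists. The correlation of the responses, 0.141, ranged from 0.0761 without gas-1 to 0.198 without mev-1. The calls of the RNAi comparison lay at low signal (median level 3.23), where arrays separate signal from background least, so genes near the filter of 2.60 limit these counts.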

Other observations

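Lists not called in the comparison of the 8 mutants with wild type are given here by their median in it. Intestine markers stood at 0.38 (11 of 13 members higher), complex II at 0.20 (4 of 5), moulting genes at 0.10, collagens at 0.09 (mean 0.25), sperm genes at 0.09, endoplasmic reticulum chaperones at 0.08, glycolysis at 0.06, antioxidant enzymes at 0.05, the glyoxylate cycle at 0.05, cytochrome P450 enzymes at 0.04, vacuolar ATPase subunits at 0.04 and the lysozyme, lectin and antimicrobial peptide list at 0.04. Proteasome subunits stood at -0.02, vitellogenins, the yolk proteins, at -0.11 and oocyte and eggshell genes at -0.11 (23 of 26 lower). For fatty acid synthesis (median -0.02, mean 0.01), HIF-1 targets (-0.09, 0.07) and DAF-16 targets (-0.01, 0.15) the median and the mean differed in sign. Their camera adjusted p-values lay between 0.0539 and 0.738, with intestine markers the lowest. In the antioxidant list, sod-3, a mitochondrial superoxide dismutase, stood at 3.30 in isp-1 and between 1.38 and 3.68 in the 5 RNAi arrays, at 0.34 in gas-1 and at -0.49 in mev-1, with 1 array each.

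The pentose phosphate list was the single list of 38 whose median in the 8 mutants, 0.36, was farther from 0 than for each of the other 23 choices of control arrays (up to 0.31), which gives an exact p of 0.0417, the smallest that 24 choices can give, and 0.528 adjusted over the 38 lists. Complex IV and the UDP-glucuronosyltransferases were matched by 1 other choice each.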
